A study of Homo sapiens with 8 samples.

How the data were processed

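ATAC-seq libraries came from U2OS cells under 2 siRNAs (siOrc6 or the control siGl3) and 2 treatments (none or 5 mM H2O2 for 30 min), with 2 libraries per condition, numbered by batch in the labels. The labels do not say whether libraries of a condition came from separate cultures. Each condition had 1 deposited peak list, whose name carries both replicate numbers, so replicates could not be compared and no test across libraries was possible. Per the submitters' processing notes, the authors' processing names bcl2fastq 2.20, Bowtie2, Picard, SAMtools, deepTools, Genrich and edgeR with genome build hg38. Those notes as used here give no role, order or threshold for any of them, and whether read positions were shifted for the transposase, or how duplicates and reads with several matches were treated, is not given in the sources used here.

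In the deposited peak lists the fifth column is a display score, and the seventh is a peak signal that the authors' caller gave to each peak; its lowest value lay just above 200.0 in every list. The eighth and ninth columns are the authors' −log10 p-value and −log10 q-value. These are the authors' values, and peak signal and −log10 p were used only to rank or filter peaks within a list. The deposited lists of changed regions give positions and a serial number, with no fold or p-value, and the threshold behind them is not given in the sources used here. Their starts lie 1 bp before those of the peaks they match. Of the regions without H2O2, 7487 of 7517 higher and 5695 of 5698 lower ones equal merged peaks of the 2 conditions joined where at most 500 bp apart. All higher regions have a siOrc6 peak and all lower ones a siGl3 peak in their own treatment. Presence there was therefore not read as a result. Whether the authors required it is not given in the sources used here.

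Peaks on chromosomes 1 to 22 and X were used. For each treatment the peaks of both siRNA conditions were merged where they overlapped or touched, and merged peaks at no changed region were the unchanged background. Regions were compared by overlap of at least 1 bp with bedtools 2.31.1. Gene positions came from a RefSeq table of assembly GRCh38.p14, which matches hg38 and lists 19970 protein-coding genes on these chromosomes. The table has no strand, transcripts or sequence. Promoters were therefore replaced by gene ends, that is within 1 kb of either annotated end of a protein-coding gene, and the planned 5 kb upstream by 5 kb on both sides. Motifs and regional GC content need a genome sequence and were not analysed here. The number of protein-coding genes per 1 Mb bin was tested in place of GC, which was chosen after seeing the data.

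Shares of regions were compared by two-sided Fisher's exact tests, with odds ratios, 95% log-scale (Woolf) intervals and Benjamini-Hochberg adjustment within each family (threshold 0.05): 4 lists for gene ends, 96 tests of 24 gene lists, 92 of chromosomes and 4 of overlaps. Intervals of shares are Wilson 95% intervals. All these intervals treat regions as independent and cover counting error only; nearby regions are not independent. Gene lists were tested against genes with a merged peak at an end, and all 690 listed genes were found in the gene table. Gene density was tested by permutation with 10000 draws of unchanged peaks of the same chromosomes. The gene-list test was checked on simulated lists: among the genes tested for untreated higher regions, a planted 3-fold excess was found in 52.8% and a 6-fold excess in 100% of cases. For untreated lower regions these were 4.8% and 25.6%.

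Named genes were chosen by a rule set before the data were examined: ORC subunits, SMARCA5, SMARCA1, BAZ1A and BAZ1B always; for each treatment and direction the first 8 protein-coding genes with a changed region at an end, by number of changed regions in the gene and 5 kb on each side, ties by total length; up to 4 members per gene list in the same order; and the 3 widest regions. Some items that this rule names are not reported here. Names beyond 4 per gene list, those hit in gene bodies, those at dense stretches and those gaining or losing peaks with H2O2 go beyond the rule and were chosen after their values were seen. Alternatives tried were stricter peaks, other overlaps, windows and backgrounds, 1 region per 100 kb and gene bodies. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Between 147 and 168 peaks per list on other sequences were left out of the comparisons.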

Results

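Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in U2OS cells, an established human osteosarcoma line. The cells received an siRNA against Orc6, the smallest subunit of the origin recognition complex that marks replication origins, or the control siRNA siGl3, for 72 h. They were held at the start of S phase by a double thymidine block, released for 3 h, and collected untreated or after 30 min in 5 mM H2O2, an oxidant that damages DNA. The 8 libraries formed 4 conditions of 2 libraries. The data analysed here were 1 list of accessible regions (peaks) per condition and 4 lists of regions that the authors called higher or lower in siOrc6 than in siGl3, without and with H2O2. No list gave a value per library, a read count or a fold change, so depth is unknown and the spread between replicates cannot be given. The exact tests below compare lists of regions or genes, which are not replicates.

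On chromosomes 1 to 22 and X, 115292 peaks were listed in untreated siGl3 cells and 109304 in untreated siOrc6 cells. With H2O2 the lists held 103674 and 97816 peaks. Peaks covered 70.3 Mb and 70.6 Mb without H2O2 and 62.8 Mb in both lists with H2O2, at median widths between 453 and 485 bp. Between 14.4% and 16.3% of peaks lay within 1 kb of an annotated end of a protein-coding gene (a gene end). Merging the 4 lists gave 129052 regions, of which 80119 (62.1%) had a peak in every condition.

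ORC1 to ORC6, SMARCA5, SMARCA1, BAZ1A and BAZ1B carried no changed region within the gene or 5 kb on each side. Over the same span, other genes of the ISWI list did: CECR2 and RBBP7 a higher one and BAZ2B and RSF1 a lower one without H2O2, and RSF1 a lower one with it. ORC6 itself (chromosome 16, 46689659 to 46698394, hg38) had 1 gene-end peak in each of the 4 lists, ranked between the 99.3 and 99.6 percentiles of its list by peak signal. An siRNA acts on the mRNA, so this peak does not check the knockdown. ORC2, ORC3, ORC4 and ORC5, the other origin subunits with a gene-end peak, had it in all 4 lists, while ORC1 had none within 1 kb. SMARCA5, the ATPase of the main ISWI remodelling complexes, and its partners BAZ1A and BAZ1B also had a gene-end peak in all 4 lists. SMARCA1, the second ISWI ATPase, had no gene-end peak in either siGl3 list and 2 in each siOrc6 list. Those overlapping the annotated end, at chromosome X, 129522976 to 129523613 without H2O2 and 129522759 to 129523623 with H2O2, ranked at the 4.63 and 38.9 percentiles of peak signal. Neither was among the regions called changed, and presence in a list was not tested.

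Without H2O2, the first comparison asked where loss of Orc6 altered accessibility in early S phase. Accessibility was higher in siOrc6 at 7517 regions and lower at 5698, against 123830 merged peaks. Genes of the replication-dependent histones, which package newly made DNA, stood out among those with more accessible ends: 13 of 35 were hit where 3.36 were expected, at 10 regions on chromosome 6. Regions lower in siOrc6 were seldom at gene ends, with 174 of 5698 (3.05%) there against 14.1% of unchanged peaks, not matched on peak signal.

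The histone genes hit were H1-1, H2AC6, H2AC12, H2AC15, H2BC4, H2BC5, H2BC12, H2BC15, H2BC17, H3C4, H4C3, H4C9 and H4C11. The odds ratio was 5.61 (95% interval 2.82 to 11.2), with an adjusted p of 0.00103 by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 96 tests of gene lists. Neighbouring histone genes shared regions: 1 of 4463 bp (27144155 to 27148617) covered ends of H2BC12 and H2AC12, and 1 of 4269 bp (26122121 to 26126389) ends of H2BC4 and H2AC6. Counted by region, 10 of 7517 higher regions lay at a histone gene end against 20 of 108532 unchanged peaks (odds ratio 7.23, interval 3.38 to 15.4, exact p = 1.16e-05). Over gene bodies with 5 kb on each side, 18 of 43 histone genes were hit and the odds ratio was 2.83 (adjusted p = 0.0417, exact test). No histone gene end was at a region lower in siOrc6, where 0.464 were expected, so this absence says little. The 10 regions were between 1203 and 4463 bp wide, against a median of 648 bp for all higher regions. The histone excess was not matched on width. How similar histone genes are in sequence was not measured here, and how reads that fit several places were treated is not given in the sources used here.

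**Figure D1:**
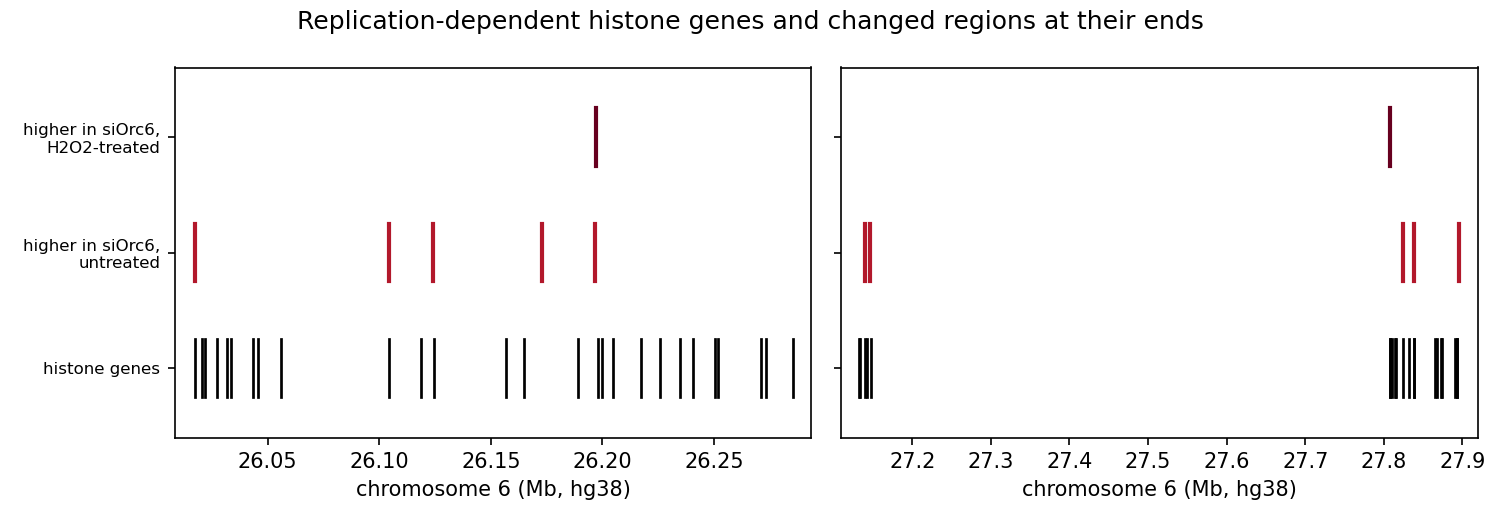
Positions of the replication-dependent histone genes of chromosome 6 (black) and of the regions at their ends that were higher in siOrc6 without H2O2 (red) and with H2O2 (dark red), in Mb of hg38; each panel has its own scale and bars mark midpoints. The 10 untreated regions are spread over the cluster; of the 2 regions with H2O2, that at H3C4 overlaps an untreated one and that at H2AC13 and H2BC13 does not.

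In total, 1360 of 14181 genes with a gene-end peak (9.59%) had a region higher in siOrc6 at an end, and 188 (1.33%) a lower one. Among genes of the antioxidant response, 7 of 30 were hit against 2.88 expected (FTH1 and FTL, the ferritin chains that store iron, with GCLM, NQO1, PRDX2, PRDX5 and TALDO1). The odds ratio of 2.88 had an exact p of 0.0209, which became 0.595 after adjustment. Genes of TGF-beta and collagen matrix gave 7 of 31, among them THBS1, VCAN, COL4A1 and COL5A1, with an adjusted p of 0.595 in the exact test. Immediate-early genes gave 6 of 29, with CCN1, DUSP1, FOSL1 and NR4A2 among them, against 2.78 expected. Origin licensing genes gave 2 of 28 (CDT1, which loads the MCM helicase, and GINS1), replication fork genes 4 of 37 (CHAF1B, CLSPN, FEN1 and POLD3) and ISWI complexes 1 of 12 (RBBP7). Repair genes gave 1 of 14 for mismatch repair (MLH3), 2 of 24 for base excision repair and 1 of 27 for double-strand breaks (XRCC5). G2/M genes gave 4 of 30, E2F and G1/S genes 3 of 23, p53 targets 4 of 26, YAP/TEAD targets 4 of 22, apoptosis genes 3 of 26, interferon-stimulated genes 3 of 23 and other chromatin remodellers 3 of 25. Ribosomal proteins gave 4 of 65, osteoblast genes 2 of 21, inflammatory genes 1 of 22 and heat shock genes 0 of 22. Genes of other cell types gave 3 of 19 (neuronal), 1 of 11 (epithelial) and 0 of 12 (blood). Some of these genes were hit through a shared region. COL4A1 and COL4A2 had 1 in common (chromosome 13, 110306323 to 110308810). FTL and BAX, counted among p53 targets and apoptosis genes, shared another (chromosome 19, 48961873 to 48966461). Among lower regions, list members included MCM7, NASP and ICAM1. Apart from the histones at higher regions, no list passed the exact test at gene ends after adjustment, in either direction.

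By number of changed regions in the gene and the 5 kb on each side, the leading genes with a more accessible end were SHROOM3, PDE1C and LRMDA (8 regions each), KAZN and ZFHX3 (7), GNG7 (6), and THBS1 and LDLRAD4 (5). The leading genes with a less accessible end were ASIC2 (7), PARD3 (6), BCAS3 and RAC2 (4), and SPTB, IGFBP2, LOC105370706 and ADAMTS12 (3). These counts cover the whole span and were not scaled for gene length, which differed widely (KAZN 13892824 to 15118043, THBS1 39581079 to 39599466). At the end of MCM7, a subunit of the replicative helicase, a region of 1502 bp (chromosome 7, 100092804 to 100094305, shared with COPS6) was lower in siOrc6 and had a peak in both siGl3 lists and in neither siOrc6 list. NASP, a histone chaperone, had a lower region of 481 bp with the same peaks. The MCM7 region lies at the end of lower coordinate (gene 100092728 to 100101397) and the NASP region at that of higher coordinate (45584041 to 45618893). Strand was not available, so whether these ends hold promoters is not known here. The widest higher region spanned 8127 bp at chromosome 21, 9001895 to 9010021, with no annotated gene. Among the widest lower regions were those inside CORO2B (4624 bp) and RAB31 (4609 bp).

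The deficit of gene ends among lower regions had an odds ratio of 0.192 (interval 0.165 to 0.223, adjusted p = 6.82e-170, Fisher's exact test). Higher regions showed a small excess, 15.6% against 14.1% (odds ratio 1.12, interval 1.05 to 1.196, adjusted p = 0.000633, exact test). That excess turned into a deficit when unchanged peaks were matched on width (odds ratio 0.770, adjusted p = 1.48e-09, exact test). Higher regions had a median width of 648 bp and lower ones of 436 bp. The excess was also lost with a 3 kb window (0.954), against unchanged peaks found in both lists (0.983) and among first-listed regions (0.331, chosen after seeing the data). It was kept in 3 other settings (1.13 to 1.28), 2 of them chosen after seeing the data. The deficit of lower regions became smaller at 3 kb (0.311). Unchanged peaks were not matched on peak signal, and only 43.9% of lower regions had an untreated siOrc6 peak. Untreated siGl3 peaks with no siOrc6 counterpart were weak (median signal percentile 13.9). They were at gene ends in 4.71% of cases, against 15.9% of shared siGl3 peaks. How much of the deficit is a trait of such weak peaks was not tested.

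**Figure D2:**
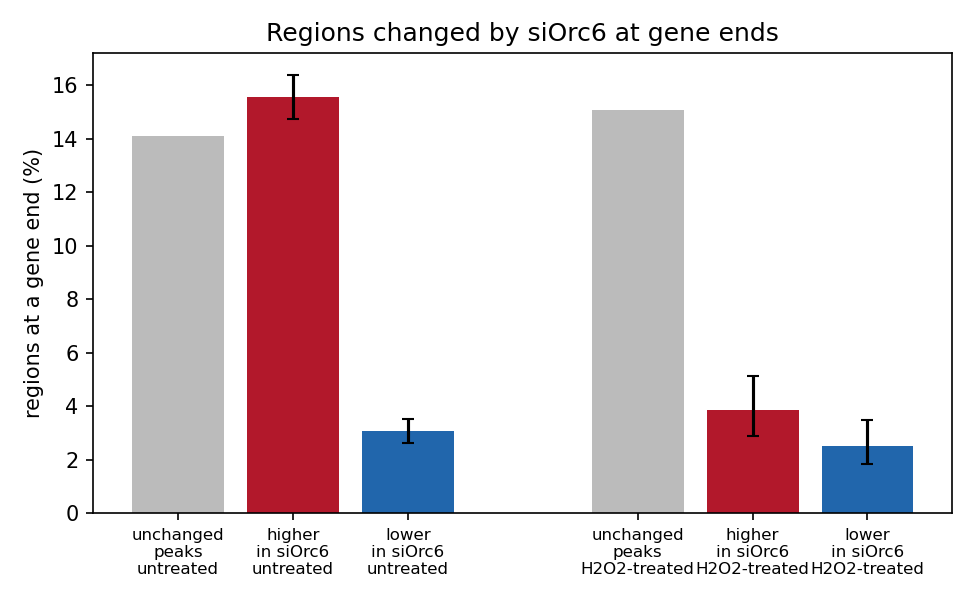
Share of regions within 1 kb of an end of a protein-coding gene (percent), for unchanged merged peaks (grey) and for regions higher (red) or lower (blue) in siOrc6; error bars are 95% Wilson intervals over regions. Only the untreated higher regions, at 15.6%, come near the unchanged peaks.

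With H2O2, the same comparison asked where loss of Orc6 altered accessibility in cells under oxidative damage. Fewer regions were listed: 1143 were higher in siOrc6 and 1464 lower, so that 13215 changed regions without H2O2 stood against 2607 with it (5.07-fold). Gene ends were under-represented in both directions, with 3.85% of higher and 2.53% of lower regions there against 15.1% of unchanged peaks. These were again not matched on peak signal. With H2O2, siGl3 peaks with no siOrc6 counterpart were at gene ends in 4.48% of cases, and siOrc6 peaks with no siGl3 counterpart in 8.98%. Histone genes were again hit among higher regions, at H2AC13, H2BC13 and H3C4 (3 of 34 against 0.115 expected).

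The odds ratios for gene ends were 0.225 (interval 0.167 to 0.305) for higher and 0.146 (0.105 to 0.202) for lower regions, with adjusted p of 2.55e-34 and 2.16e-57 in Fisher's exact test; for lower regions it was 0.233 with a 3 kb window and 0.234 against peaks matched on width. The histone list had an odds ratio of 30.3 (interval 8.93 to 103, adjusted p = 0.00978, exact test). It rests on 2 regions, since H2AC13 and H2BC13 shared 1 (27806648 to 27808577). Counted by region, 2 of 1143 higher regions lay at a histone gene end against 34 of 107712 unchanged peaks (odds ratio 5.55, interval 1.33 to 23.1, exact p = 0.0549). That count also changes the background, from genes with a gene-end peak to all unchanged peaks, and these higher regions were seldom at gene ends. The weaker value is therefore not due to the shared region alone. Over gene bodies with 5 kb on each side, the odds ratio was 4.62 and the adjusted p 0.0709 in the exact test. At gene ends, no other list passed. Apart from histones, STAT2, a mediator of interferon signalling, was the single member of any gene list with an end at a higher region, and no list member had an end at a lower one. These lists held 48 and 39 genes with a changed end, and on simulated lists of that size a planted 6-fold excess was found in 1.6% and 3.2% of cases, so that excesses of this size were mostly not detectable.

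Other genes with a more accessible end under H2O2 were LRMDA (3 regions), NFE2L3, a relative of the antioxidant regulator NRF2, and SMG6 (2), and TENT4B, SLC25A1, PIGV, CRKL and SIM2 (1 each). Genes with a less accessible end were RSPH14, LOC105370706 and TSHZ2 (2 regions each) and CCDC116, BCR, CRB2, LRRC3 and CHI3L1 (1 each). BCR and RSPH14 shared a region of 1592 bp at chromosome 22, 23178333 to 23179924. The widest higher regions lay in GNG7 (4095 bp), in ZNF608 (3896 bp) and at the end of TENT4B (3434 bp). Among the widest lower regions were those in MAPK8IP3 (4798 bp) and on chromosome 22 with GRK3 as the nearest coding gene, 75.6 kb away.

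Regions changed by siOrc6 with H2O2 were largely those changed without it, in the same direction. Of 1143 higher regions with H2O2, 816 (71.4%) overlapped one higher without H2O2, among them those at LRMDA, NFE2L3, TENT4B, SIM2, STAT2 and H3C4. Of 1464 lower regions, 890 (60.8%) overlapped one lower without H2O2, among them those at LOC105370706, TSHZ2, CRB2 and CHI3L1. Conversely, 815 of 7517 higher regions without H2O2 (10.8%) and 890 of 5698 lower ones (15.6%) overlapped one listed in the same direction with it. No region changed in opposite directions. Over 129052 merged peaks, 863 were higher in both, where independent lists would share 83.5 (odds ratio 36.4, interval 32.1 to 41.3), and 913 were lower in both, against 72.8 (odds ratio 34.5, interval 31.0 to 38.3). Among the 80119 merged peaks found in all 4 lists, these odds ratios were 55.7 and 156. Against 105 and 57.8 expected, 0 were shared in the opposite directions (adjusted p = 5.54e-48 and 3.11e-26, Fisher's exact test). The 2 comparisons used different libraries, but their library numbers name the same 2 batches.

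**Figure D3:**
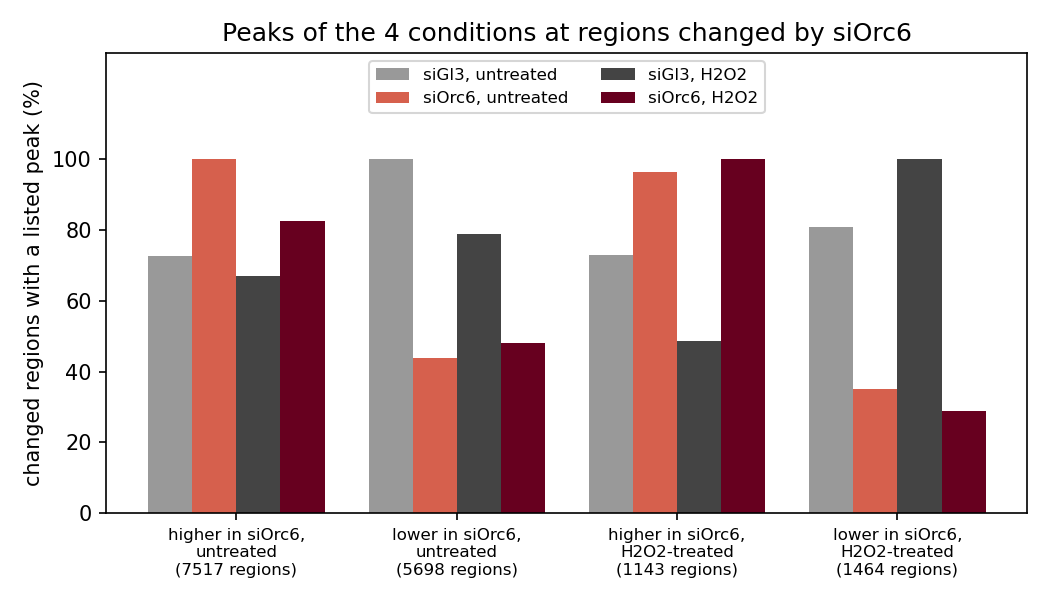
Share of changed regions (percent) with a listed peak in each of the 4 conditions, for the 4 lists of regions. All regions higher in siOrc6 have a siOrc6 peak and all lower ones a siGl3 peak in their own treatment; in the other treatment the same siRNA keeps the higher share.

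The share of gene ends among higher regions differed between treatments, 15.6% without and 3.85% with H2O2 (odds ratio 4.60, adjusted p = 4.71e-33, Fisher's exact test). For lower regions, 3.05% and 2.53% did not differ detectably (adjusted p = 0.340, exact test). The untreated list is longer, and the share varied along it: with the list in 10 parts of about 752 regions, 3.19% of the first part lay at gene ends and 23.1% of the fifth. The first 1143 untreated regions had 5.16% at gene ends (interval 4.02% to 6.60%), against 3.85% (2.88% to 5.13%) of the 1143 with H2O2, an odds ratio of 1.36 with an exact p of 0.158.

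**Figure D4:**
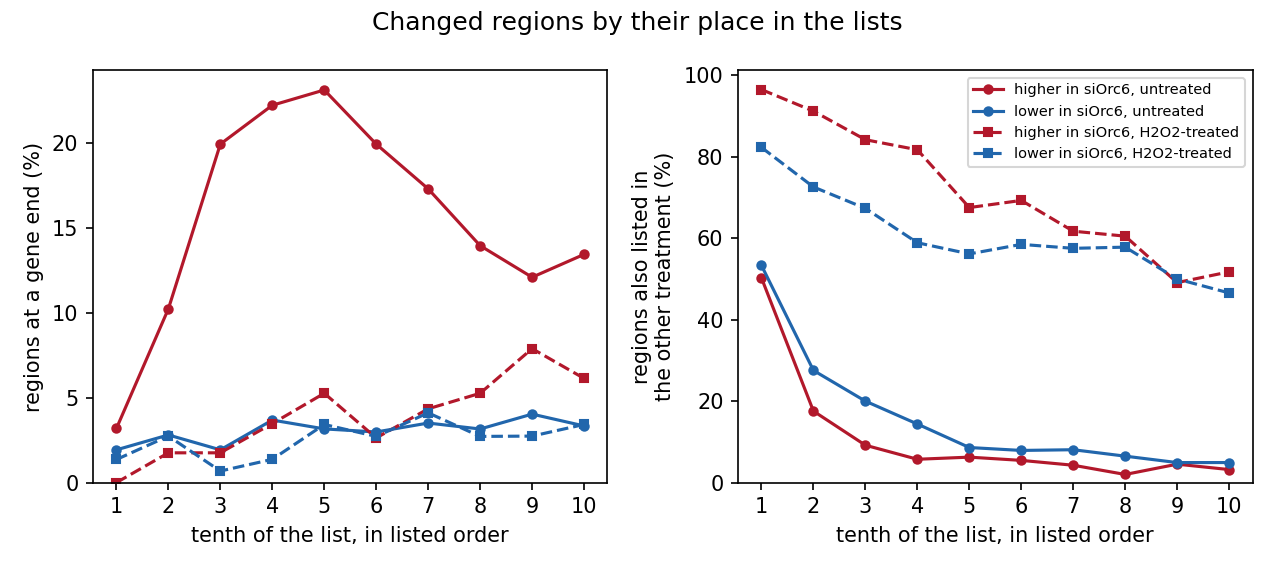
Left, share of changed regions at gene ends (percent); right, share also listed in the same direction in the other treatment (percent), both over 10 equal parts of each list in listed order. Untreated higher regions rise from 3.19% at gene ends in the first part to 23.1% in the fifth, while the share found in the H2O2 list falls from 50.3% in the first to 3.196% in the last.

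The effect of H2O2 itself could be read only from which peaks were listed, with no test, since each condition had 1 list. H2O2 lists lacked 17.05% of siGl3 peaks and 16.9% of siOrc6 peaks found without it, while 7.96% and 7.06% of H2O2 peaks had no untreated counterpart. Peaks listed only without H2O2 were seldom at gene ends (4.93% in siGl3 and 4.69% in siOrc6, against 16.3% and 17.1% of shared peaks). Those found only with H2O2 were at gene ends in 11.97% and 11.5% of cases. Condition-specific peaks were weak, with a median signal percentile between 10.9 and 13.9 of their own list. Of 129052 merged regions, 6268 were listed only without H2O2 in both siRNA conditions, against 2614 for independent lists, and 1865 only with H2O2, against 411. At the level of genes, 91 had a gene-end peak only without H2O2 and 121 only with it in both siRNA conditions. These include peaks whose edge moved across the 1 kb limit, as at VCAN, where the region at the gene end had a peak in all 4 lists. Other members of the gene lists with a gene-end peak only without H2O2 were IFI44L and CD2, and those with one only with H2O2 were BMP2 and CDH11, both of the bone lineage, with CLDN7, CD79A, HBA1 and IKZF1. Gene ends of replication fork (37 of 37), base excision repair (24 of 24), mismatch repair (14 of 14) and ribosomal protein genes (65 of 67) had a peak in all 4 lists.

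Regions changed by siOrc6 were compared with peaks listed only without or only with H2O2. Of regions lower in siOrc6 without H2O2, 21.3% were at a siGl3 peak listed only without H2O2, against 15.3% of unchanged peaks and 9.09% of higher regions. With siOrc6 peaks the order turned, at 6.02% of lower regions, 14.6% of unchanged peaks and 17.6% of higher regions. Of regions higher in siOrc6 with H2O2, 25.5% lay at a siGl3 peak listed only without H2O2, against 4.45% of unchanged peaks, and 19.1% of lower ones lay at a siGl3 peak listed only with H2O2, against 7.18%. Every changed region had a peak in its own treatment on the side where it was higher, which sets part of these shares, and the lists share libraries, so no test was made.

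Changed regions were unevenly spread over chromosomes. Regions higher in siOrc6 were over-represented on chromosome 4 both without H2O2 (5.40% against 4.22% of unchanged peaks, adjusted p = 5.65e-05, exact test) and with it (6.91% against 4.01%, adjusted p = 9.35e-05, exact test), and under-represented on chromosome 17. Lower regions were over-represented on chromosomes 2 and 8 and under-represented on chromosome 19 in both treatments. On chromosome 8 they made up 6.74% against 5.37% without H2O2 and 7.24% against 5.31% with it. With 1 region per 100 kb, the number of chromosomes past the threshold for higher regions fell from 7 to 4 without H2O2 and from 4 to 1 with it, while that for lower regions went from 7 to 9 and from 3 to 4. Of the calls named above, only the excess of lower regions on chromosome 2 without H2O2 then stayed past the threshold (odds ratio 1.16, adjusted p = 0.0423, exact test). Among calls not named above, the deficit of lower regions on chromosome X without H2O2 went from 0.575 to 0.354 (adjusted p = 5.65e-05 and 1.06e-17, exact test). That on chromosome 4 went from 0.796 to 0.590 (adjusted p = 0.0107 and 6.95e-10, exact test). The odds ratio of higher regions on chromosome 17 with H2O2 went from 0.466 (interval 0.316 to 0.689) to 0.736 (0.488 to 1.11). Without H2O2, those of higher regions on chromosomes 4 and 17 and of lower regions on chromosome 19 turned from 1.296, 0.781 and 0.672 to 0.872, 1.19 and 1.17, none of these past the threshold. There the background moved and the changed regions hardly did. On chromosome 4, unchanged peaks went from 4.22% to 6.15% and higher regions from 5.40% to 5.41%. On chromosome 17 these were 4.55% to 2.98% and 3.59% to 3.53%. For lower regions on chromosome 19 they were 3.49% to 2.14% and 2.37% to 2.48%. Higher regions also lay where genes are sparse: their 1 Mb bins held a mean of 8.66 protein-coding genes without H2O2, against 10.1 for unchanged peaks of the same chromosomes, and 6.76 against 10.3 with H2O2. Lower regions had 9.12 against 10.2 and 8.22 against 10.4. All 4 had an adjusted p of 0.0002 in a two-sided permutation test of 10000 draws, the smallest these can give.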

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

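The comparison of first-listed regions in this part was chosen after the result was seen, and the draws at matched widths were set before it.

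The share of gene ends among regions higher in siOrc6 differed between treatments, with an odds ratio of 4.60 for untreated against H2O2-treated cells in an exact test of the difference itself. Wider untreated regions do not account for all of it: untreated regions drawn to the widths of the H2O2 list had a median of 10.3% at gene ends over 1000 draws (7.61% to 12.6%), above the 3.85% with H2O2 and its upper bound of 5.13%. List length may account for it, since the first 1143 untreated regions had 5.16% at gene ends, within overlapping intervals. This reading takes listed order as a ranking, which the files do not state. At equal length the exact test gave an odds ratio of 1.36 (p = 0.158), which does not show equal shares, so an effect of H2O2 on the response of gene ends stays open.

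Peaks on sequences other than chromosomes 1 to 22 and X were not used in the comparisons. They numbered 147 in untreated siGl3 cells, 168 in untreated siOrc6 cells, 160 in siGl3 cells with H2O2 and 168 in siOrc6 cells with H2O2. No changed region was listed on them.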

How the results depend on the processing

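Joining unchanged peaks at 500 bp, counting gene ends only where a gene had a peak at 1 end, taking the first-listed regions, counting gene lists by region and all gene density values were chosen after seeing the data. Peak counts stayed within 1.5 times, and the deficits of gene ends (odds ratios 0.103 to 0.319), gene density (ratios 0.605 to 0.9499) and overlaps between treatments (same direction 34.5 to 156, opposite directions 0) kept their direction and side of the threshold under the alternatives run. No alternative for gene ends matched unchanged peaks on peak signal. Merging changed regions within 500 bp (7517 to 7513) or keeping those at a peak moved next to nothing, so these say little. Of 164 alternative values, those outside the main results included 13 that moved, 4 that kept their direction and passed the threshold only there, and 8 that lost it. Shares of peaks found in the second list moved beyond their intervals for siGl3 without and with H2O2, siOrc6 without and with H2O2, untreated siGl3 and siOrc6, and H2O2-treated siGl3 and siOrc6. With 50% of both peaks they were 75.8%, 76.1%, 78.8% and 80.9%, with the 30000 top peaks 86.5%, 88.5%, 88.31% and 90.4%, and with stricter peaks 84.9%, 84.5%, 88.33% and 89.0%. The gene-end odds ratio of untreated higher regions turned from 1.12 to 0.954 (3 kb), 0.770 (matched on width), 0.983 (background in both lists) and 0.331 (first-listed regions), and stayed above 1 and past the threshold with 1 region per 100 kb (1.28), peaks joined within 500 bp (1.17) and genes with a peak at 1 end (1.13). The match on width drew on merged peaks not joined at 500 bp, while most changed regions equal joined ones. Width and joining thus cannot be separated for that value, and for the others the cause was not tested. Over gene bodies with 5 kb on each side, 5 tests of gene lists passed without H2O2 (histones in both directions) and 2 with it (neuronal genes in both directions), against 1 and 1 at gene ends. There neuronal genes turned from no hit to odds ratios of 4.50 (untreated, lower), 8.79 (H2O2, higher) and 5.94 (H2O2, lower). Counted by region, TGF-beta and collagen matrix genes at untreated lower regions turned to 0.501 from 1 region. With 1 region per 100 kb, chromosomes past the threshold for higher regions fell from 7 to 4 without H2O2 and from 4 to 1 with it, while for lower regions they went from 7 to 9 and from 3 to 4. Of the calls for higher regions on chromosomes 4 and 17 and lower regions on chromosomes 2, 8 and 19, all but 1 ended there. Without H2O2 the odds ratios turned to 0.872 and 1.19 (higher, chromosomes 4 and 17) and 1.17 (lower, chromosome 19). In these turns the share of unchanged peaks moved and that of changed regions hardly did (chromosome 4, 4.22% to 6.15% against 5.40% to 5.41%). For the other calls the cause was not tested. No paired analysis was possible because each condition had 1 list for both replicates, and for the same reason no replicate could be left out. Not run: a stricter fold or p for changed regions (none is listed), promoter definitions that need strand or transcripts, and all motif and GC alternatives (no genome sequence used here). Unknown depth limits every list: a region absent from a list may lie just under its threshold.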

Other observations

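The E2F test, the test of regions listed in 1 treatment, the tests of tRNA and lncRNA genes and the dense stretches were chosen after the result was seen, gene bodies were chosen beforehand, and the rotation of genes was set before its result.

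Inside genes and their 5 kb flanks, regions lower in siOrc6 without H2O2 touched 11 of 33 genes of TGF-beta and collagen matrix (4.53 expected, adjusted p = 0.0466, Fisher's exact test), among them COL1A1, COL5A1, FBN2, SPARC and TGFB2. They touched 10 of 24 neuronal genes (3.30 expected, adjusted p = 0.0234, exact test), among them DLG2, GRIN2A, GRIN2B and NRXN3, and 0 of 65 ribosomal protein genes (8.93 expected, adjusted p = 0.00931, exact test). Histone genes were touched by no lower region either (0 of 43, 5.91 expected, adjusted p = 0.0466, exact test). At gene ends the adjusted p of these 4 lists at lower regions was 1; counted by region, ribosomal protein gene ends were at 0 of 5698 lower regions and 98 of 108532 unchanged peaks (unadjusted exact p = 0.0164, odds ratio interval 0.00600 to 1.56). Higher regions touched 13 of 33 genes of TGF-beta and collagen matrix (6.71 expected, adjusted p = 0.127, exact test) and 9 of 24 neuronal genes (4.88 expected, adjusted p = 0.282, exact test), with COL5A1, DLG2, GRIN2B and NRXN3 touched in both directions. With H2O2, neuronal genes were touched by higher regions (5 of 25) and by lower ones (5 of 25), and gene length was not taken into account. Without H2O2, 0 of 5698 lower regions came within 500 bp of a tRNA gene, against 213 of 108532 unchanged peaks (adjusted p = 0.000354, exact test). Without H2O2, ends of lncRNA genes were at 4.41% of lower and 8.55% of higher regions, against 7.67% of unchanged peaks (adjusted p = 4.91e-21 and 0.0288, exact test). With H2O2 they were at 4.10% of lower and 5.16% of higher regions, against 8.07% (adjusted p = 2.44e-08 and 0.00115, exact test). The background of these tRNA, lncRNA and ribosomal protein counts by region was all unchanged peaks, not matched on position at gene ends. Lower regions in both treatments, and higher ones with H2O2, were seldom at ends of protein-coding genes in general. Whether tRNA genes, lncRNA ends or ribosomal protein gene ends show a deficit beyond this general one was not tested. The background was not matched on width either. For untreated higher regions, the small excess at protein-coding gene ends turned into a deficit against peaks matched on width. Whether their lncRNA excess would remain was not tested.

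Some stretches were dense in changed regions. On chromosome 19, 27 to 28 Mb, which holds no protein-coding gene in the table, 18 regions were higher in siOrc6 without H2O2 and 12 with it, at 21 of 31 and 14 of 24 merged peaks. On chromosome 8, 142 to 143 Mb, 21 regions were lower without H2O2, at 26 of 242 merged peaks, and 133 to 134 Mb, with CCN4, NDRG1 and ST3GAL1, held 20.

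Histone genes with more accessible ends without H2O2 numbered 13. Runs of changed neighbouring genes like those elsewhere in the genome do not account for this. As many were hit in 0.0776% of rotations of the changed genes along the genome (11 of 14181, the real order included, and the highest other gave 14). Rotation does not reproduce sharing particular to the packed histone genes, so it cannot exclude that. With each shared region counted once, the odds ratio against all unchanged peaks was 7.23 (interval 3.38 to 15.4), a count chosen after seeing the data. A larger share of cells in S phase may raise histone genes. E2F and G1/S genes left this open, with an odds ratio of 1.415 and an interval from 0.420 to 4.77. Replication fork genes gave 1.14 (0.404 to 3.23) and origin licensing genes 0.725 (0.172 to 3.06), which leave it open as well. Reads shared between histone copies and the width of these regions were not tested, nor was an effect of Orc6 loss on these genes apart from S phase.

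Fewer regions were called with H2O2. Of 6702 regions listed as higher only without H2O2, 4574 had a peak in both siRNA lists with H2O2, 1296 in neither and 832 in 1; of these 832, 96.8% had it in siOrc6 (805), against 38.2% of unchanged peaks. Of 4808 listed as lower only without H2O2, 1249 had a peak in 1 list, and 98.2% of these had it in siGl3 (1227), against 61.8%. Every higher region had an untreated siOrc6 peak and every lower one an untreated siGl3 peak, while unchanged peaks were not restricted in this way. Among merged peaks listed untreated only in siOrc6, and with H2O2 in 1 list, that list was siOrc6 for 1973 and siGl3 for 508. For those listed untreated only in siGl3, these were 445 and 4674, and for those in both, 4261 and 4350. Part of the contrast thus follows from the untreated peaks, and what remains was not tested. Regions with a peak in both lists or in neither were not assessed. A smaller difference with H2O2 and a weaker test with fewer reads cannot be separated without counts, and batches named alike in both treatments stay open as well.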
